A study of Mus musculus with 12 samples.

How the data were processed

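The deposited table holds raw counts per gene for 12 libraries, 4 groups of 3, and the totals per library in the report are sums of these counts over all 55401 genes. Per the labels' protocols, live cells of adult C57BL/6 liver were sorted as CD45+ CD3+ NK1.1− CD4− CD8− and TCRαβ+ or TCRγδ+ before the stimulation with AA for 48 h, RNA was taken with Trizol, and libraries were made with an Illumina TruSeq kit from 1 µg of total RNA. Per the submitters' processing notes the reads were handled with Bowtie 0.12.2 and the genome build mm8. The program that counted reads, its annotation and its use of strand are not given in the sources used here. Of the identifiers, 98.1% match the GENCODE M21 annotation with their version, which is of a later build than mm8, so no coordinates are given. Gene symbols came from the GENCODE M21 table of names, which matched 55141 of the 55401 identifiers without regard to version; the other 260 stayed unnamed. Without a stated strand setting, counts of overlapping genes and of near-identical copies, such as the TCR γ constant regions, the granzymes and the Klra and Bcl2a1 families, are uncertain.

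Libraries were grouped by their labels alone. Whether replicates were separate animals or cultures is not stated. Counts of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 52.4 to 268, so none was taken as a copy of another. The comparisons were AA against no AA in each population, the difference of these effects, and γδ against αβ without and with AA. Tests, samples, gene lists, the rule for named genes and most alternatives were set before the data were examined.

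Genes were kept by edgeR's filterByExpr (minimum count 10), which left 22107. Libraries were scaled by TMM, and all 12 entered one model with a mean per group and 8 residual degrees of freedom. Genes were tested with glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. The common biological coefficient of variation was 1.21. Group means in CPM use TMM scaling with SD, and values of single libraries are CPM of all counts; errors of log2 fold changes are SE. Ratios of genes with few counts have an exact 95% interval, and a gene with no count in a group was given a floor of 3 counts over the group; both cover counting error only.

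A total of 36 lists, 22 of pathways and 14 of cell markers, held 702 genes, of which 694 were matched and 8 were not. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and at least 3 measured members. The gene members were also adjusted over each list alone. Several lists share members. The lists of sort gates test what the sort selected, and the lists were not chosen on these samples.

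The rule for named genes took, for the AA comparisons and the comparison without AA, the 10 genes with the largest fold change in each direction among those past the threshold, without overlap of the groups and with a mean of at least 5 CPM in the higher group, predicted genes left out. For the difference of effects it took 5 in each direction. Where none passed, it took the 5 with the smallest p in each direction. In each list it took up to 4 called members or, failing those, 2 with the smallest p. The genes Trac, Trbc1, Trbc2, Trdc, Cd4, Cd8a, Klrb1c, Il17a, Ifng, Gzmb, Prf1, Fasl, Bcl2 and Il10 were always named. List members past the threshold adjusted over the list alone were named as well. Some genes that the rule takes are not reported here.

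Alternatives were DESeq2's size factors and library size alone as scaling, no filter and a filter of 5 CPM in 3 libraries, a fold threshold, the replicate number as a block, only the groups compared, DESeq2 1.42.0, camera with an estimated correlation, fry, and each library left out in turn. Added after the data were seen were limma's voom with quality weights, robust estimation, omission of the libraries labelled replicate 3 without AA in both populations, omission of the repeat genes Gm10800 and Gm21738 (Gm10800 took 21.9% of the counts of αβ with AA replicate 3) and thinning to the smallest total for lists. For lists, the other scalings, the stricter filter and left-out libraries were also added then, as were left-out libraries for the correlation of AA effects and for the bounds of Lrrc2 and Inca1.

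The tests were first run on simulated counts for the 22107 genes, with 200 genes changed. At a log2 fold change of 3 the share recovered was 43% for AA in αβ, 45% for AA in γδ, 16% for their difference, 36% between populations without AA and 50% with AA. At a log2 fold change of 1 it was at most 1%. With every gene given the median dispersion of genes at 50 CPM or more, the shares at 3 were 100%, 97%, 76%, 99% and 100%. Genes of lower expression did not enter that median, so these shares do not hold for a typical tested gene. A shifted list was found in each by camera with the preset correlation, at p of 5.72e-05 or less. The simulated genes were drawn independently, so this does not test lists whose genes vary together. Each simulated gene also had the same dispersion in all groups, while real replicates of αβ with AA were less alike than the others. The shares recovered may thus not hold for comparisons that use αβ with AA.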

Results

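RNA was sequenced from mouse hepatic T cells that carry CD3 but neither CD4 nor CD8, known as double negative (DN) T cells. Cells from adult C57BL/6 liver were sorted by flow cytometry into a population bearing the αβ T cell receptor (TCR) and a population bearing the γδ receptor, both CD45+ CD3+ NK1.1−. Each population was measured with and without arachidonic acid (AA), the fatty acid from which prostaglandins and leukotrienes are made, to find genes that differ with it. Stimulation lasted 48 h per the labels, which do not say whether the libraries without AA came from cells cultured as long, so differences with AA may include those of culture. The series concerns DN T cells in fatty liver disease not caused by alcohol. The 4 groups held 3 libraries each, and gene counts summed to 21616779, 21189619 and 30548253 per library for αβ without AA and to 8988771, 17021782 and 6036487 for αβ with AA. The γδ libraries held 19327567, 24145149 and 20983619 counts without AA and 18301268, 23461265 and 18781074 with AA. The αβ libraries with AA were the shallowest, so their low values carry the largest counting error. Correlations of log2 CPM (counts scaled to a common library total) within a group ranged from 0.560 to 0.691 for αβ with AA and from 0.803 to 0.899 over the other groups. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. That spread was estimated per gene over all groups together, although replicates of αβ with AA were less alike than the others.

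Among the receptor genes, which check the labels, Trdc contradicted them in the third libraries without AA, while those of the α and β chains did not separate the populations without AA. Trdc (ENSMUSG00000104876.1), the constant region of the TCR δ chain, stood at 3.70 and 5.90 CPM of all counts in αβ without AA replicates 1 and 2, but at 201 CPM in the library labelled replicate 3. In γδ without AA it stood at 246 and 265 CPM in replicates 1 and 2, but at 11.6 CPM in the library labelled replicate 3. With AA it stood at 55.4, 5.35 and 52.8 CPM in the αβ libraries and at 208, 197 and 69.8 CPM in the γδ libraries. Per count of the CD3 genes Cd3d, Cd3e and Cd3g, Trdc stood at 0.354 in the library labelled αβ without AA replicate 3 and at 0.358, 0.131 and 0.227 in αβ with AA replicates 1, 2 and 3, against 0.0178 and 0.0243 in αβ without AA replicates 1 and 2. It stood at 0.0292 in the library labelled γδ without AA replicate 3 and at 0.230 to 0.518 in the other γδ libraries. By this measure the αβ libraries with AA also lay toward γδ, though in replicate 2 the ratio rested on 91 Trdc and 693 CD3 counts. The TCR γδ list made up 0.0742%, 0.0749% and 0.0762% of all counts in αβ with AA and 0.145%, 0.181% and 0.0780% in γδ with AA. The CD3 and CD45 genes of the sort gate also made up less in αβ with AA, at 0.0946%, 0.0854% and 0.0921%. Without AA they made up 0.137%, 0.140% and 0.170% in αβ. A share of all counts is thus not on the basis of the Trdc ratio and does not argue against it. The TCR γδ list as a whole made up 0.129% of the counts in the library labelled αβ without AA replicate 3, between the 0.0686% and 0.0842% of the other two and the 0.257% and 0.204% of γδ without AA replicates 1 and 2, and 0.0748% in the library labelled γδ without AA replicate 3. The α and β constant regions made up 0.153%, 0.137% and 0.154% in αβ without AA and 0.139%, 0.173% and 0.177% in γδ without AA. With AA they made up 0.0384%, 0.0209% and 0.0567% in αβ and 0.153%, 0.239% and 0.155% in γδ. Trac (ENSMUSG00000076928.5), the α chain constant region, was abundant in γδ as well as αβ libraries, at 497 ± 145 CPM in αβ without AA and 343 ± 186 CPM in γδ without AA (n = 3 each). With AA, Trac was at 82.0 ± 44.8 CPM in αβ and 530 ± 140 CPM in γδ. Lyz2 (ENSMUSG00000069516.8), the lysozyme of myeloid cells, was present in all 12 libraries although the sort was on CD3. Lyz2 stood at 22782 CPM in the library labelled αβ without AA replicate 3 against 1857 and 1672 CPM in the other two, and at 3626 CPM in the library labelled γδ without AA replicate 3 against 35050 and 11235 CPM. The genes behind the negative gates were low: Cd4 had group means of 0.136 to 1.45 CPM, Cd8a 0 to 6.60 CPM and the NK1.1 gene Klrb1c 1.69 to 7.64 CPM. Samples were kept in the groups their labels give, so every direction below that uses a group without AA includes a library whose Trdc level contradicts its label. With AA, the α and β constant regions were lower in the libraries labelled αβ than in those labelled γδ, against their labels.

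**Figure D1:**
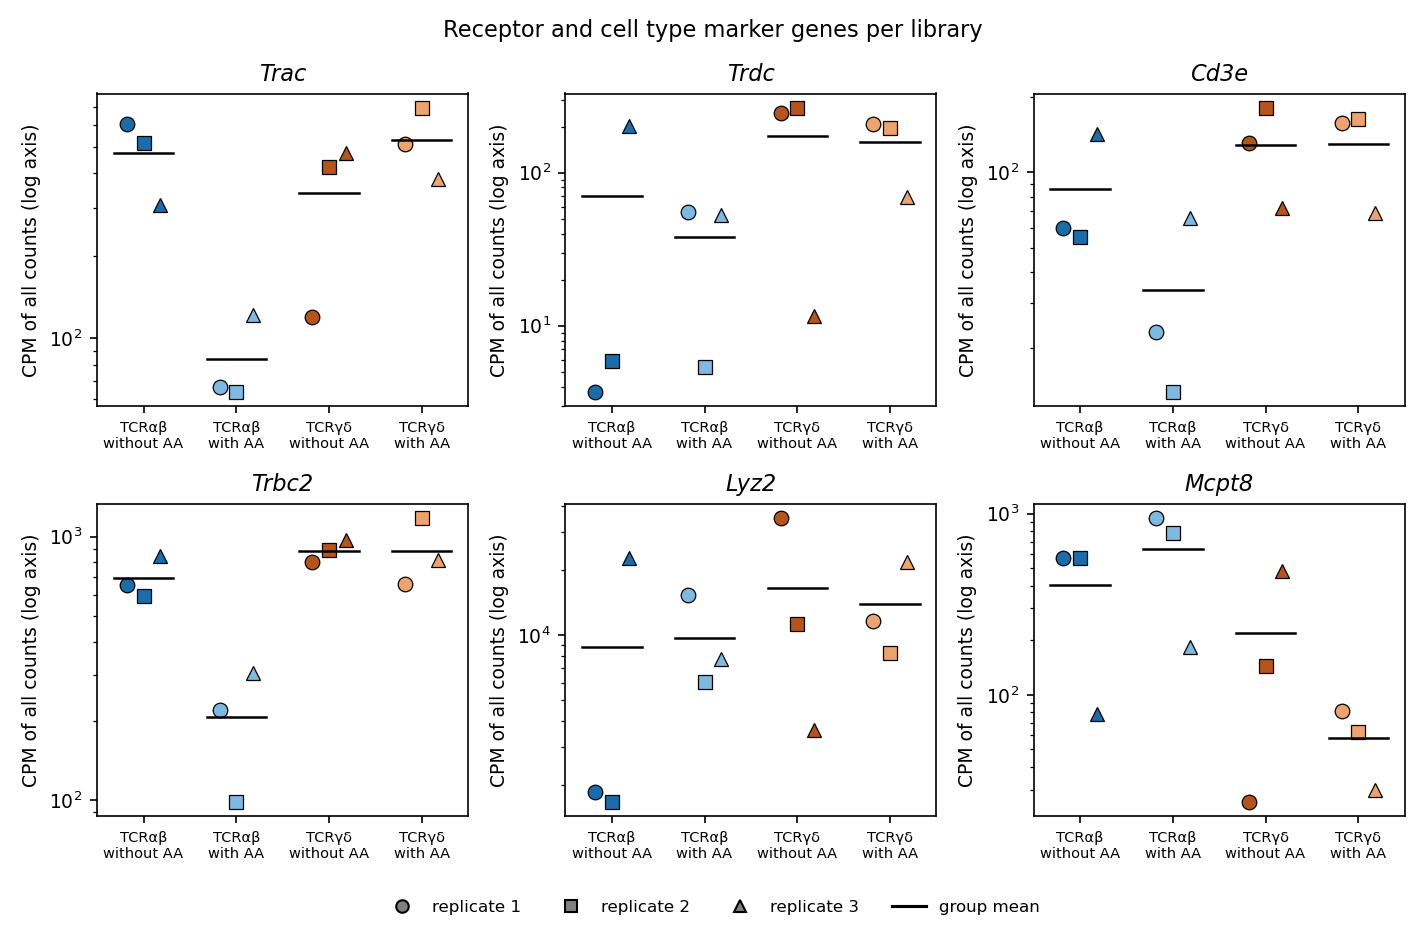
CPM of all counts (log axis) of Trac, Trdc, Cd3e, Trbc2, Lyz2 and Mcpt8 in each of the 12 libraries, with points for libraries and lines for group means. The libraries labelled replicate 3 without AA lie across their labels for Trdc, at 201 CPM in αβ and 11.6 CPM in γδ.

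In the libraries labelled αβ, AA went with the near absence of Tbx21 and Wdr89 and a lower level of Lck. Tbx21 (ENSMUSG00000001444.2), which encodes T-bet, the transcription factor of type 1 immunity, had 2668 counts in the 3 libraries without AA and 1 count in the 3 with AA, a ratio of 1357 (exact 95% counting interval 243 to 53622). Its mean level was 0.0606 ± 0.105 CPM with AA against 36.6 ± 14.6 without (n = 3 each). Wdr89 (ENSMUSG00000045690.8), a WD repeat gene, was at 0.106 ± 0.184 CPM against 33.4 ± 4.37, a log2 fold change of −7.84 ± 1.07 (SE). Lck (ENSMUSG00000000409.14), the kinase that starts TCR signalling, fell to 73.7 ± 16.0 CPM from 375 ± 29.3, a log2 fold change of −2.35 ± 0.33. These 3 genes were the ones past the threshold among 22107 tested, all lower with AA, each at an adjusted p of 0.0377 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The fitted log2 fold change of Tbx21, −9.85 ± 1.30, depends on the prior count. An unadjusted p under 0.05 was reached by 2263 genes, against 1105 by chance, and DESeq2 called 366 genes, 277 higher and 89 lower. The balance turned with the setting, at 47 higher and 217 lower with no filter on low counts, 48 and 13 by voom, and 0 and 76 without αβ with AA replicate 2. The count of 3 fell to 0 with DESeq2's size factors, with library size alone, with the stricter filter and in a fit of only the groups compared, and to 0 without any of the 3 αβ libraries without AA or without αβ with AA replicate 1. It was 1 without γδ without AA replicate 3, 6 without αβ with AA replicate 3 and 76 without αβ with AA replicate 2, and 0 when both libraries whose Trdc levels contradict their labels were left out.

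Genes fixed beforehand for their role in DN T cells did not pass the test in αβ libraries. Trac had a log2 fold change of −2.60 ± 0.49 and Trbc2, a β chain constant region, −1.88 ± 0.39, with adjusted p of 0.146 and 0.163 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The cytokine gene Il17a was at 124 ± 101 CPM with AA and 413 ± 320 without, a log2 fold change of −1.73 ± 0.68, and Il10, an anti-inflammatory cytokine, at 42.1 ± 12.4 and 14.6 ± 5.77 CPM, a log2 fold change of 1.53 ± 1.15. The killing genes Prf1, Gzmb and Fasl had log2 fold changes of −3.14 ± 1.19, −1.29 ± 1.15 and −2.54 ± 1.36, the survival gene Bcl2 −0.78 ± 0.50, and Ifng, the type 1 cytokine, −4.04 ± 2.33. Over these 6 genes and Il10 the smallest adjusted p was 0.424 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Trdc and Trbc1 had log2 fold changes of −1.09 ± 1.30 and −1.81 ± 0.41.

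Among the fixed gene lists, 18 fell and 1 rose with AA in the libraries labelled αβ, out of 36 tested by camera with a preset correlation and Benjamini-Hochberg adjustment. None was called with an estimated correlation (0 of 36, smallest adjusted p = 0.162). Mitochondrial genes made up 5.43%, 4.53% and 2.54% of the counts in αβ with AA against 2.48%, 2.27% and 1.09% without, and mt-Rnr2, a mitochondrial ribosomal RNA, was the top gene in αβ with AA replicates 1 and 2. In γδ their share was 1.64%, 2.62% and 2.29% with AA and 2.27%, 1.52% and 3.06% without. The proliferation list fell (median log2 fold change −0.82, 30 of 34 members lower, adjusted p = 9.75e-06), and adjusted over the list alone 10 members passed, among them the replication helicase gene Mcm7 (−1.16 ± 0.29) and the mitotic checkpoint gene Bub1b (−1.81 ± 0.46). Glycolysis genes fell (median −0.51, 23 of 29 lower, adjusted p = 0.000814), with 7 members past the threshold adjusted over the list alone, led by the lactate dehydrogenase gene Ldha at 513 ± 209 against 1618 ± 256 CPM, but their median lay inside the range of random lists of like expression (−0.67 to −0.17). The list of T cell activation and NF-κB genes had all 28 members lower (median −0.86, adjusted p = 2.63e-05), Myc and Tnfrsf9 having the smallest p, and the cholesterol synthesis list all 25 (median −0.78, adjusted p = 2.63e-05), among them Sqle at 97.2 ± 8.49 against 194 ± 14.5 CPM. Type 1 genes fell by a median of 1.16 (16 of 18 lower, adjusted p = 3.71e-05), with 4 members past the threshold adjusted over the list alone, Tbx21, Il2rb, Klrd1 and Stat4. The cytotoxicity list fell (median −1.28, 19 of 23 lower, adjusted p = 0.000275), with Ctsw at 47.0 ± 27.1 against 236 ± 129 CPM, as did the inhibitory receptor list (median −0.92, 17 of 23 lower, adjusted p = 0.000503), with Pdcd1 and Lag3 among the 6 members past the threshold adjusted over the list alone. For each of these 7 lists the camera adjusted p was 0.162 with an estimated correlation. Random lists of like expression also fell, with middles of −0.41, −0.43, −0.45, −0.39, −0.27, −0.22 and −0.37 in the order above. Part of each median may thus reflect a trend over all genes. Apart from glycolysis, the medians lay below the range of such random lists.

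Further lists fell with AA in the libraries labelled αβ. Interferon response genes had a median of −1.24 (23 of 28 lower, adjusted p = 0.000165), type 17 genes −0.82 (17 of 20, 0.000366), the TCR α and β constant regions −1.88 (3 of 3, 0.000826) and oxidative phosphorylation genes −0.62 (30 of 35, 0.00175), all by camera with Benjamini-Hochberg adjustment. The stress response list, with Shmt2 (200 ± 54.8 against 550 ± 49.7 CPM) and the serine synthesis gene Phgdh, had a median of −0.56 (22 of 27 lower, camera adjusted p = 0.00205). The genes that promote apoptosis, with Trp53 at 182 ± 18.7 against 374 ± 32.7 CPM, had a median of −0.50 (18 of 23 lower, camera adjusted p = 0.00566). The CD3 and CD45 genes of the sort gate were lower in all 5 members (median −1.30, camera adjusted p = 0.0206). Heat shock genes had 9 of 12 members lower and a median of −0.81, but a mean of 0.06 (camera adjusted p = 0.0279). The lists of genes against apoptosis (median −0.80), of chemokine receptors and adhesion (−0.37) and of naive and memory T cells (−0.35) fell at a camera adjusted p of 0.0459 each, and the medians of the chemokine receptor and the naive and memory lists turned positive with DESeq2's size factors, which shift all genes by 0.39. The medians of the oxidative phosphorylation, stress response, apoptosis-promoting, chemokine receptor, and naive and memory lists lay inside the range of random lists of like expression, and those of the last pair lay above its middle (−0.41 and −0.46). Endothelial and stellate genes rose (median 1.33, 10 of 12 higher, camera adjusted p = 0.0459), but this median too lay inside the range of random lists of like expression (−0.56 to 1.70), and the call ended whichever library was left out. With an estimated correlation the adjusted p of these 12 lists lay at 0.162 or above. The call held whichever library was left out for 11 of the 19 lists, and 11 lists were called without αβ with AA replicate 2. That library's removal ended the calls of oxidative phosphorylation and type 17 genes. The sort gate, heat shock and chemokine receptor calls ended without either αβ with AA replicate 2 or αβ without AA replicate 3. The list against apoptosis was lost without αβ without AA replicate 3 or αβ with AA replicates 1 or 2, and the naive and memory list without αβ with AA replicates 2 or 3. DESeq2's size factors moved the median of all genes by 0.39 in this comparison, and library size alone by 0.20, from 0.12 under the main scaling.

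The remaining 17 lists did not pass in the libraries labelled αβ, including those nearest to lipid handling. Genes of fatty acid oxidation had a median of −0.32 (camera adjusted p = 0.146), fatty acid synthesis −0.43 (0.0702), LXR targets −0.24 and prostaglandin and leukotriene genes 0.47 (0.786). Within the last, the prostacyclin receptor gene Ptgir was at 88.0 ± 17.2 CPM with AA and 21.9 ± 8.68 without, past the threshold adjusted over the list alone but not over all genes (adjusted p = 0.265 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In the type 2 list, Gata3, the transcription factor of type 2 immunity, was at 9.74 ± 6.28 against 77.9 ± 17.4 CPM, likewise past the threshold only adjusted over the list alone. The medians of the type 2, NRF2, TCR γδ, hepatocyte and NK cell lists were −0.36, 0.12, −0.85, 0.08 and −0.31. Those of the B cell, macrophage, mast cell and erythroid lists were −0.13, 0.03, 0.80 and 0.17. The dendritic cell list had a median of −0.15 and a mean of 0.36, the neutrophil list a median of −0.11 against a test pointing up, and the lists of the negative sort gate and of sex genes −0.15 and −0.01.

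**Figure D2:**
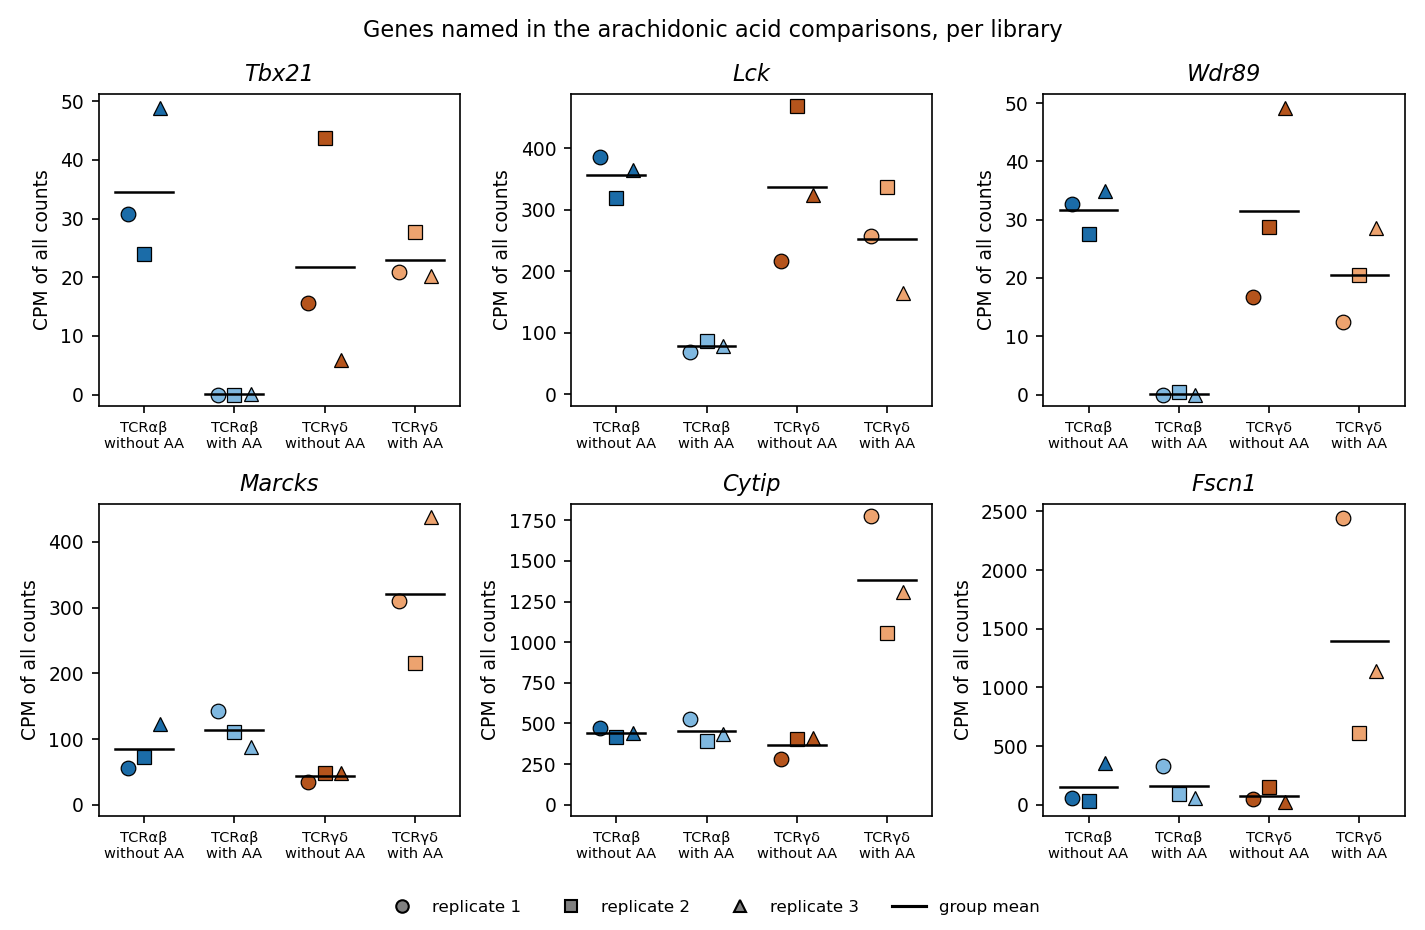
CPM of all counts (linear axis) of Tbx21, Lck, Wdr89, Marcks, Cytip and Fscn1 per library in the 4 groups, with points for libraries and lines for group means. Tbx21 and Wdr89 lie near 0 in the 3 αβ libraries with AA, while Marcks and Cytip are highest in the 3 γδ libraries with AA.

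In the libraries labelled γδ, Marcks and Cytip rose with AA. Marcks (ENSMUSG00000069662.5), an actin-binding substrate of protein kinase C, reached 326 ± 123 CPM from 44.9 ± 6.54 (n = 3 each), a log2 fold change of 2.86 ± 0.38. Cytip (ENSMUSG00000026832.12), which regulates adhesion of leukocytes through cytohesin, reached 1394 ± 384 CPM from 375 ± 56.0, a log2 fold change of 1.89 ± 0.25. They were the 2 genes past the threshold, each with an adjusted p of 0.0347 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The chemokine receptor gene Ccr7, which guides cells to lymph nodes, was at 3849 ± 1194 CPM with AA and 558 ± 278 without, and Serpinb9, an inhibitor of granzyme B, at 1627 ± 484 and 149 ± 68.8 CPM. Both missed the threshold, with an adjusted p of 0.105 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was reached by 1600 genes against 1105 by chance, and DESeq2 called 279 genes, 189 higher and 90 lower. Without both libraries whose Trdc levels contradict their labels, 5 genes rose: Serpinb9, Ramp3, Apol7c, Marcks and Ccr7. The count was 0 without γδ without AA replicates 1 or 3 or γδ with AA replicates 1 or 3, and 6 without γδ with AA replicate 2. It was 5, 5 and 7 without αβ without AA replicates 1, 2 and 3, and without γδ without AA replicate 2 it was 2 with neither Marcks nor Cytip among them. A fit of only the groups compared called 3 genes, with neither Marcks nor Cytip among them.

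The fixed effector genes did not pass the test in the libraries labelled γδ. Il17a was at 338 ± 220 CPM with AA and 186 ± 109 without, and Il10 at 4.65 ± 4.12 and 2.54 ± 0.95 CPM. The log2 fold changes of Ifng, Gzmb, Prf1, Fasl and Bcl2 were −0.09 ± 2.05, −0.68 ± 1.13, −0.05 ± 1.09, 0.40 ± 1.28 and −0.58 ± 0.50. Those of the receptor genes Trac, Trbc1, Trbc2 and Trdc were 0.63 ± 0.46, −0.05 ± 0.39, −0.04 ± 0.38 and −0.20 ± 1.28. The smallest adjusted p over these genes was 0.772 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

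Of the fixed lists, 5 fell and 4 rose with AA in the libraries labelled γδ by camera with a preset correlation and Benjamini-Hochberg adjustment. None was called with an estimated correlation (0 of 36), the adjusted p being 0.229 for proliferation and 0.636 or above for the other 8. The library γδ with AA replicate 3 stood apart, correlating at 0.803 with replicates 1 and 2 against 0.899 between those. It also had the lowest quality weight by voom (0.413). The proliferation list fell (median −1.03, 33 of 34 members lower, camera adjusted p = 7.86e-14), with 9 members past the threshold adjusted over the list alone, among them Tk1 at 47.4 ± 7.04 against 126 ± 53.4 CPM and Ube2c at 36.4 ± 3.18 against 94.7 ± 23.2 CPM. Genes of the NRF2 response to oxidative stress rose (median 0.73, 21 of 27 higher, camera adjusted p = 8.62e-07), with Nqo1 at 141 ± 110 against 16.5 ± 11 CPM past the threshold adjusted over the list alone. The activation and NF-κB list rose (median 0.36, 21 of 28 higher, camera adjusted p = 0.000711), with the NF-κB subunit genes Rel (434 ± 118 against 120 ± 56.3 CPM) and Relb higher, and Myc lower, past the threshold adjusted over the list alone. In the same libraries 25 of 28 genes of mature dendritic cells, a list added after the data were seen and without the leading genes seen by then, were higher with AA (median 1.46), and that list shares Relb, Traf1, Tnfrsf4 and Icam1 with the activation list. Neutrophil genes rose as a list (median 2.25, 14 of 15 higher, camera adjusted p = 1.72e-05), though no member passed even adjusted over the list alone. Lcn2 was at 32.3 ± 34.8 against 3.83 ± 1.80 CPM, and S100a8 stood at 506 CPM in γδ with AA replicate 3 and at 49.1 and 51.7 CPM in replicates 1 and 2. Type 17 genes rose as a list (median 0.25, 14 of 20 higher, camera adjusted p = 0.0498), though no member passed even adjusted over the list alone. Il17f was at 309 ± 75.7 against 117 ± 63.6 CPM. B cell genes fell (median −1.41, 12 of 13 lower, camera adjusted p = 0.00106), as did oxidative phosphorylation genes (median −0.42, 31 of 35, 0.0205), macrophage genes (median −1.62, 14 of 14, 0.0498) and interferon response genes (median −0.67, 19 of 28, 0.0498). The proliferation, NRF2, neutrophil and activation calls held whichever library was left out, and 5 lists were called without γδ without AA replicate 1. The B cell call ended without γδ without AA replicate 3, whose Trdc level contradicts its label. The oxidative phosphorylation call ended without γδ without AA replicate 1 or γδ with AA replicates 1 or 2. The type 17 call ended without γδ without AA replicates 1 or 2 or γδ with AA replicates 2 or 3. The interferon call ended without αβ with AA replicates 1 or 2, γδ without AA replicate 1 or γδ with AA replicate 2, and the macrophage call without αβ with AA replicate 3, γδ without AA replicates 1 or 2 or γδ with AA replicates 1 or 2.

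Outside the lists called, single members passed in the libraries labelled γδ when adjusted over the list alone. Ptger4, the prostaglandin E2 receptor EP4, was at 125 ± 87.5 CPM with AA and 28.4 ± 12.4 without, and Pfkfb3, a regulator of glycolysis, at 358 ± 179 and 62.3 ± 34.3 CPM. Neither of these passed over all genes, with adjusted p of 0.431 and 0.300 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The medians of the lipid lists were −0.12 for fatty acid oxidation, 0.23 for fatty acid synthesis, 0.02 for cholesterol synthesis, 0.06 for LXR targets and −0.33 for prostaglandin and leukotriene genes. Among the other lists not called, medians were −0.68 for cytotoxicity, −0.42 for inhibitory receptors, 0.21 for type 1, 0.43 for type 2, 0.07 for glycolysis and 0.13 for the stress response. The mean of the dendritic cell list was 0.70 and its median −0.35, and the means of the LXR, prostaglandin and leukotriene lists, −0.28 and 0.27, also had the opposite sign to their medians. For the fatty acid oxidation and TCR γδ lists the test pointed up against negative medians.

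**Figure D3:**
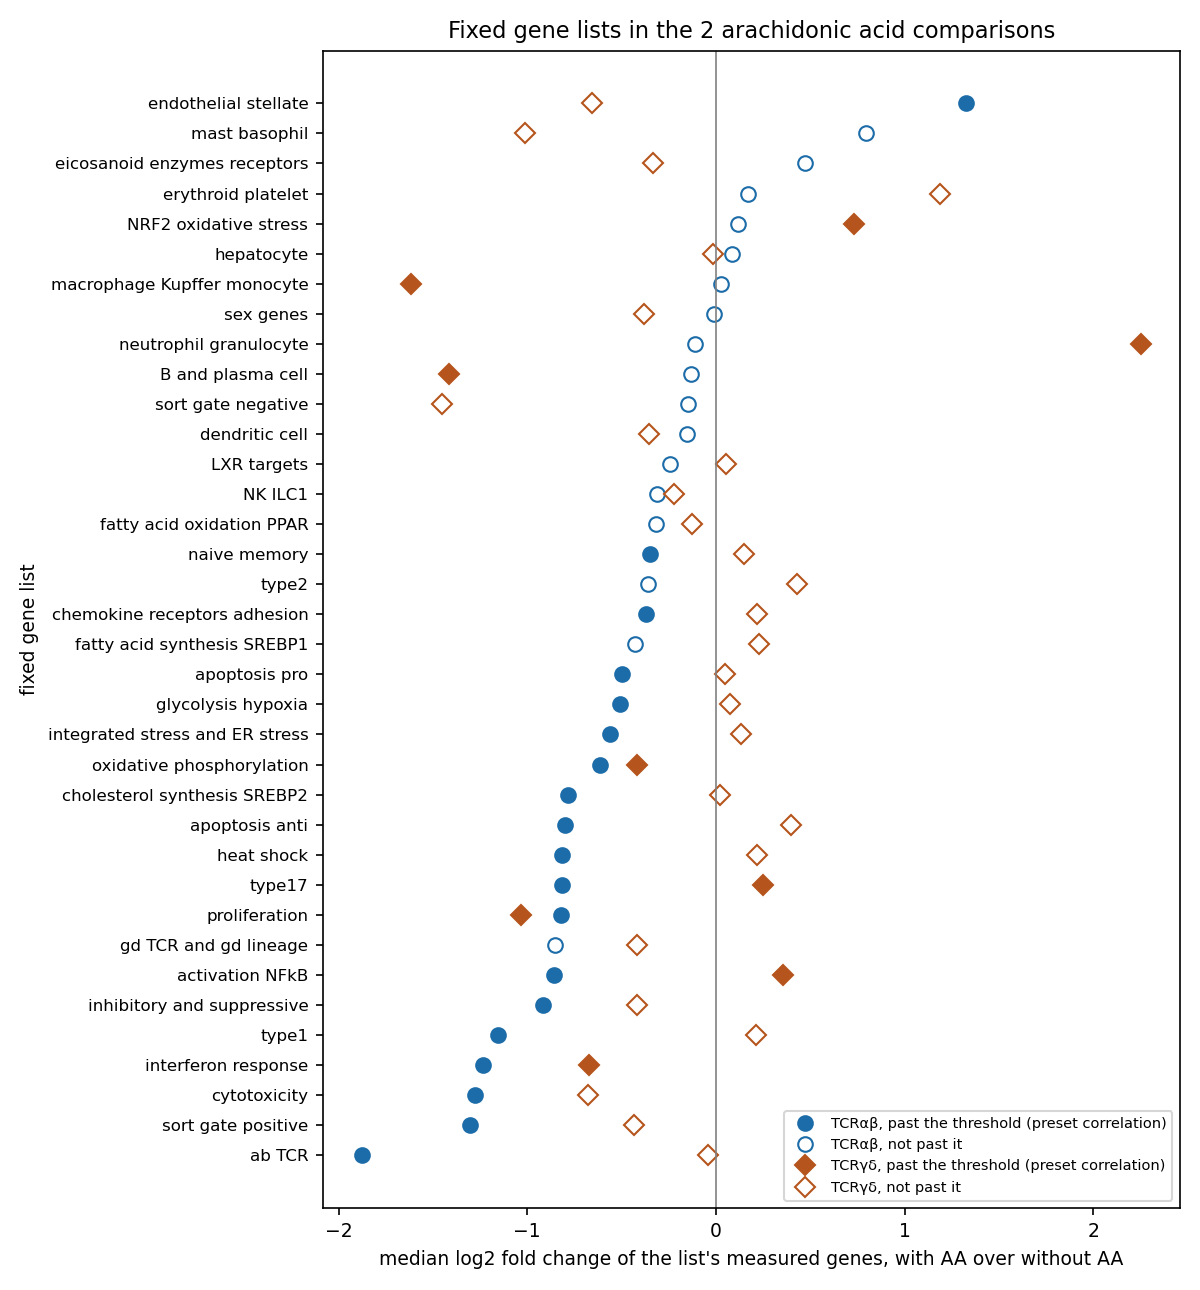
Median log2 fold change with AA of each of the 36 fixed lists in the libraries labelled αβ and γδ, with filled points for lists past the threshold by camera with a preset correlation. No list passed in either comparison with an estimated correlation. The proliferation list lies at −0.82 and −1.03 and the activation list at −0.86 in αβ and 0.36 in γδ, while the medians of the chemokine receptor and naive lists in αβ turn positive with DESeq2's size factors.

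The difference between the AA effects of the 2 populations was tested directly. The genes with the smallest p were Cytip, with a log2 difference (γδ minus αβ) of 2.04 ± 0.35, the adaptor gene Samsn1 with 2.60 ± 0.44, Tbx21, Wdr89 and Sema4f. Samsn1 stood at 407 ± 91.9 CPM in αβ with AA and 733 ± 201 without, and at 1208 ± 412 CPM in γδ with AA and 358 ± 59.6 without. In the other direction were Inca1, Lrrc2, Inhba, Olfr652 and Iqgap3, of which Iqgap3 had a log2 difference of −5.11 ± 1.17 and the other four had a group at or near 0. No gene passed (0 of 22107), the smallest adjusted p being 0.211 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was reached by 2117 genes and DESeq2 called 321. The count was 48 without αβ with AA replicate 2 and 1 without αβ without AA replicate 2.

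For lists, 15 differed upwards and 3 downwards, γδ minus αβ, by camera with Benjamini-Hochberg adjustment. With an estimated correlation none passed (0 of 36, smallest adjusted p = 0.135). The activation list had all 28 members with a higher log2 fold change in γδ (median 1.42, adjusted p = 1.04e-08), type 17 genes 16 of 20 (median 0.96, 3.04e-05) and type 1 genes 14 of 18 (median 1.30, 4.91e-05). Glycolysis, cholesterol synthesis and stress response genes had medians of 0.78, 0.97 and 0.60. B cell, endothelial and macrophage genes had medians of −1.51, −1.86 and −1.36, and NRF2 genes 0.66. Without both libraries whose Trdc levels contradict their labels, the calls for B cell (median −0.0806, camera adjusted p = 0.572) and NRF2 genes (median −0.127, 0.962) were lost. Proliferation did not differ past the threshold (median −0.16, camera adjusted p = 0.811). Across genes, which are not independent replicates, the correlation of fold changes with AA between the populations was 0.000607 (Pearson; Spearman 0.0205, 22107 genes), and Pearson's r was 0.108 with the stricter filter on low counts. Of genes with an unadjusted p under 0.05, 108 were lower in both populations, against 51.2 for independent lists, and 74 were higher in both, against 31.6. Both tests share 1 estimate of each gene's spread, which alone can raise such overlaps. Overlap in opposite directions was not counted, so these numbers do not show a shared response. No called gene was shared (0 by edgeR's quasi-likelihood test in either direction).

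Without AA, the libraries labelled γδ and αβ were compared to describe the populations in the absence of AA. By camera with a preset correlation 7 lists were called, and none with an estimated correlation (0 of 36, smallest adjusted p = 0.623). The TCR γδ list was higher in γδ (median 1.17, 9 of 10 members, camera adjusted p = 0.00345), with Trdc at 182 ± 147 against 76.4 ± 124 CPM and Sox13, a transcription factor of γδ T cells, at 51.4 ± 41 against 10.4 ± 4.75 CPM. Macrophage genes were higher (median 0.93, 12 of 14, camera adjusted p = 0.000333), as were oxidative phosphorylation genes (median 0.30, 0.00234), NRF2 genes (median 0.19, 0.0269) and the genes of the positive sort gate (median 0.70, 5 of 5, 0.0269). Stress response genes were lower (median −0.34, 23 of 27, camera adjusted p = 0.0173), with Atf4 at 548 ± 106 against 861 ± 200 CPM. The neutrophil list was called higher (camera adjusted p = 0.0112) with a median of −0.06 and a mean of −0.48. No gene passed (0 of 22107, smallest adjusted p of 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The count at an unadjusted p under 0.05 was 729, fewer than the 1105 of chance, and DESeq2 called 79. The genes with the smallest p included Il7r, the IL-7 receptor, at 411 ± 189 against 180 ± 46.8 CPM, and Crip1 at 117 ± 24.2 against 47.9 ± 26.3 CPM. Lower in γδ were Samsn1 (log2 −1.03 ± 0.31) and Nfil3 (−1.45 ± 0.48). Lrrc2 and Inca1 had no count in any αβ library without AA and were at least 129-fold and 187-fold higher in γδ, taking 3 counts over the group as the floor. The bound of Lrrc2 fell to 25.8-fold without γδ without AA replicate 1, which held 13.2 CPM against 1.04 and 1.19 CPM in the other two. Trac, Trbc1 and Trbc2 had log2 differences of −0.53 ± 0.46, 0.39 ± 0.40 and 0.31 ± 0.38, and Il10 was at 2.54 ± 0.95 against 14.6 ± 5.77 CPM.

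Leaving out the 2 libraries whose Trdc levels contradict their labels changed the comparison without AA. Then 6 genes were higher in γδ, all of myeloid or granulocyte cells: the lysozyme gene Lyz2 (log2 3.72), the growth factor receptor gene Csf1r (3.72), Clec4a2 (7.04), the granule genes Prg2 (3.93), Prtn3 (4.08) and Elane (4.06). With all libraries these differences were 0.91, 0.44, 0.99, 0.52, 0.06 and 0.02. The number of lists called rose from 7 to 12. List counts also moved with single libraries: 11 without αβ without AA replicate 3, 2 and 1 without αβ without AA replicates 1 and 2, 0 without γδ without AA replicate 1 and 4 without γδ without AA replicate 2. No list call here held whichever library was left out.

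With AA, F2r, Tbx21, Wdr89, Apol7e and Cytip were higher in the libraries labelled γδ than in those labelled αβ. These 5 genes, all that passed, lay outside the rule for named genes and were chosen after their values were seen. F2r (ENSMUSG00000048376.6), the thrombin receptor, was at 198 ± 26.4 against 26.9 ± 8.61 CPM (n = 3 each), with an adjusted p of 0.0217 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tbx21 had 1414 counts against 1, a ratio of 829 (exact 95% counting interval 148 to 32750), and Wdr89 had 1245 counts against 6, a ratio of 122 (55.7 to 332). Apol7e (ENSMUSG00000071716.5), an apolipoprotein L gene, was at 33.2 ± 10.2 against 0.659 ± 0.513 CPM, and Cytip at 1394 ± 384 against 421 ± 62.9 CPM. The adjusted p of these 4 genes was 0.0369 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Genes at an unadjusted p under 0.05 numbered 4080, 1369 higher and 2711 lower. DESeq2 called 1824 genes, 354 higher and 1470 lower, but no filter on low counts gave 376 higher and 296 lower, and omission of αβ with AA replicate 2 gave 145 and 8. The count was 0 with DESeq2's size factors, library size alone, the stricter filter or only the groups compared, and 27 without the 2 libraries in doubt. It was also 0 without αβ without AA replicate 1, αβ with AA replicate 1 or γδ with AA replicates 1 or 3. It was 153 without αβ with AA replicate 2, 21 without αβ with AA replicate 3, 14 without αβ without AA replicate 3 or γδ with AA replicate 2, and 3 without γδ without AA replicate 2.

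With AA, 20 lists were higher and 3 lower in the libraries labelled γδ by camera with a preset correlation and Benjamini-Hochberg adjustment. None of the 23 passed with an estimated correlation (0 of 36, smallest adjusted p = 0.113). Type 17 genes were higher (median 1.29, 18 of 20 members, camera adjusted p = 2.38e-07), with 10 members past the threshold adjusted over the list alone, among them Il7r (536 ± 111 against 119 ± 61.7 CPM) and Cxcr6 (454 ± 112 against 91.5 ± 67.5 CPM). Activation genes (median 1.11, 26 of 28, camera adjusted p = 1.18e-06) and type 1 genes (median 1.74, 14 of 18, 1.70e-05) were higher, as were the inhibitory receptor genes (median 0.70, 17 of 23, 0.00207), with Pdcd1 at 424 ± 75.4 against 79.0 ± 52.3 CPM. The TCR α and β constant regions were higher in γδ (median 2.15, 3 of 3, camera adjusted p = 0.000685), as was the TCR γδ list (median 1.79, 9 of 10, 0.00207), Trdc itself having a log2 difference of 2.14 ± 1.34. The genes of the positive sort gate were higher by a median of 1.72 (camera adjusted p = 0.00275), and neutrophil genes by 2.01 (0.00261). The TCR constant regions and sort gate genes thus differed by more than the type 17, activation and inhibitory receptor lists. A lower share of T cells in αβ with AA may contribute to these calls, which was not tested. B cell genes were lower (median −2.28, 12 of 13, camera adjusted p = 0.00207), as were endothelial and stellate genes (median −2.13, 0.00400) and the mast cell and basophil list (median −3.37, 7 of 8, 0.0305). In the last, Mcpt8, a protease of basophils, was at 58.1 ± 25.8 against 561 ± 313 CPM. The mast cell call ended without any of 10 libraries, all but αβ without AA replicate 3 and αβ with AA replicate 3, and the B cell call without αβ with AA replicate 2. The stress response list, called higher with a median of 0.28, lost its call without αβ with AA replicate 3 and had a median of −0.03 with DESeq2's size factors, which shift all genes by −0.31.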

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

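The tests of RNA from other cells and of T cell content given in this part, and the choice of gene number in the test of library positions, were chosen after the result was seen. Left-out libraries and thinning for lists were added after the data were seen; the tests of position, depth and level were otherwise chosen before their results.

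The following lists had AA effects that differed between the populations by a test of the difference itself, with medians given as γδ minus αβ; all calls were lost with an estimated correlation (adjusted p from 0.135 to 0.630). Higher in γδ were the TCR α and β constant regions (1.84), activation and NF-κB (1.42), type 1 (1.30), chemokine receptors and adhesion (1.02), cholesterol synthesis (0.97), heat shock (0.97) and type 17 (0.96). So were inhibitory receptors (0.88), genes against apoptosis (0.85), naive and memory (0.83), cytotoxicity (0.82), glycolysis (0.78), NRF2 (0.66), genes for apoptosis (0.60) and stress response (0.60). Lower in γδ were endothelial and stellate (−1.86), B cell (−1.51) and macrophage (−1.36) genes. Of the lists higher in γδ, the TCR α and β constant regions had the largest median. The positive sort gate list had a median of 0.84 and was not called. A lower share of T cells in αβ with AA may contribute to these differences, which was not tested. Without both libraries whose Trdc levels contradict their labels, the calls for B cell (median −0.0806, camera adjusted p = 0.572) and NRF2 genes (median −0.127, 0.962) were lost. The B cell difference ended on leaving out any of 8 libraries, the macrophage difference any of 9, NRF2 any of 5 and endothelial any of 4. The chemokine receptor difference ended without αβ without AA replicate 3 or αβ with AA replicate 2, and that of inhibitory receptors without αβ with AA replicate 2. Among 60 splits, those of the libraries drawn with the real one included, 2 gave 18 lists or more, a share under 0.05, and the highest of the others was 18. Drawn splits that kept the αβ groups and mixed the γδ ones gave 13, 17, 18 and 17 lists. Those that kept the γδ groups and mixed the αβ ones gave 3, 12 and 3. The count thus rests mainly on the αβ grouping, and the share says little about a difference between the effects. For genes the real count was 0, which any split reaches (60 of 60, highest other 9), so the splits decide nothing.

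Trdc in the third libraries without AA lay across their labels, while the α and β constant regions did not separate the groups without AA and decide nothing. On 200 genes that separate replicates 1 and 2 of the 2 groups, with the receptor and other marker lists left out, the library labelled αβ replicate 3 stood at 1.02 and the library labelled γδ replicate 3 at 0.297, on a scale of 0 for αβ and 1 for γδ, a difference of 0.722 (0.502 to 0.790 over other numbers and levels of genes). An exchange of these libraries is a candidate explanation; other genes of myeloid cells remain in that set. RNA of cells that lack both Trdc and CD3 genes is argued against, since Trdc per Cd3 count in the library labelled αβ replicate 3 was 14.6 times the higher of the other two, while that of γδ replicate 3 was 0.0808 times the lower. The αβ libraries with AA also lay toward γδ, at positions of 0.700, 0.163 and 0.568 and with 0.358, 0.131 and 0.227 Trdc per CD3 count. Their TCR γδ list made up 0.0742%, 0.0749% and 0.0762% of all counts, near the 0.0686% and 0.0842% of αβ without AA replicates 1 and 2. That share does not allow for the lower share of CD3 and CD45 genes in these libraries, so it does not counter the Trdc ratio. The presence of γδ T cells in libraries labelled αβ thus stays open, untested. Labels were kept, and no biological explanation was tested.

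Most lists called in the libraries labelled αβ fell with AA. Lower depth stays open as a part of the cause, since 14 of the 19 lists kept their call after thinning to the smallest total, just short of the share set beforehand for excluding it. A trend with expression level stays open, since 6 of the 18 lower lists lay inside the range of random lists of like expression. These were glycolysis, oxidative phosphorylation, stress response, genes for apoptosis, chemokine receptors, and naive and memory, while 12 lists lay below it. Genes under a mean log2 CPM of 0 had a median log2 fold change with AA of 1.95 in αβ and 0 in γδ. Those over 8 had medians of −0.56 and −0.10. Libraries of αβ held counts for 25693 ± 4814 genes with AA and 23785 ± 4437 without, despite the lower depth with AA. In γδ they held counts for 18879 ± 1188 and 20712 ± 1496 genes. The cause of these patterns was not tested. A lower share of T cells may also contribute and stays open: 7 T cell genes had a median of −1.41 (SD 0.55) and no called list without T cell receptor or sort gate genes fell further, the next being cytotoxicity at −1.28. An effect of AA on these cells, which the design names, remains untested against these and against a difference in culture.

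Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For AA in αβ, 1 split, the real one, gave as many as 3 genes (highest other 0) and 1 as many as 19 lists (highest other 14). For AA in γδ the real split alone gave 2 genes (1 of 10, highest other 0) and 9 lists (1 of 10, highest other 6). Without AA the real count of 0 genes is reached by any split (10 of 10, highest other 10), which decides nothing, and 4 splits reached the real 7 lists (highest other 18). That highest split sets αβ replicates 1 and 2 and the library labelled γδ replicate 3 against the other three, which points to a structure of the samples other than their labels. With AA, 2 splits reached the real 5 genes (highest other 15) and 1 the real 23 lists (highest other 12). The split with 15 genes sets αβ replicates 1 and 3 and γδ replicate 3 against the rest, and it called 0 lists. These libraries correlated with each other at only 0.560, 0.588 and 0.650, so the split does not show a group of like samples.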

How the results depend on the processing

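The settings with voom, robust estimation, without Gm10800 and Gm21738 and without the libraries labelled replicate 3 without AA (in doubt for their Trdc) were chosen after seeing the data, as were, for lists, both scalings, the stricter filter, thinning and left-out libraries, and left-out libraries for the correlation of AA effects. Counts of genes are given in the order AA in αβ (3), AA in γδ (2), their difference (0), γδ against αβ without AA (0) and with AA (5). DESeq2 gave 366, 279, 321, 79 and 1824 genes, no filter 264, 146, 217, 12 and 672, and voom with quality weights 61 and 21 for the AA effects and 712 with AA. Without the libraries in doubt the counts were 0, 5, 0, 6 and 27. Robust estimation gave 40 with AA. The split of higher against lower calls was 277 to 89 by DESeq2, 47 to 217 with no filter and 48 to 13 by voom for AA in αβ, and 354 to 1470, 376 to 296 and 91 to 621 with AA. Scaling by DESeq2's size factors, scaling by library size, the stricter filter and a fit of only the groups compared each left 0 genes for AA in αβ and 0 for γδ against αβ with AA; the scaling shifts of all genes were 0.39 and 0.20 for the former and −0.31 and −0.14 for the latter. The replicate block left 0 genes in each of these comparisons and for AA in γδ, where only the groups compared gave 3 genes and neither of the 2 main calls; same-numbered libraries deviated with correlations of −0.18 to 0.14, above 0.1 in 2 of 12 pairs, so the numbers were not taken as pairs. Leaving out single libraries gave 0 to 76, 0 to 7, 0 to 48, 0 to 0 and 0 to 153 genes, and 11 to 21, 5 to 9, 12 to 23, 0 to 11 and 21 to 25 lists. Lists (19, 9, 18, 7 and 23) numbered 0 in each comparison with an estimated correlation. By fry they were 16, 1, 3, 0 and 17. With the stricter filter they were 12, 11, 12 and 12 for AA in αβ, the difference, without AA and with AA, and without the libraries in doubt 12 without AA. The correlation of AA effects (0.000607) was 0.108 with the stricter filter and −0.0922 to 0.0708 with single libraries left out. Over the 5 genes called in either it was 0.729, but these genes were chosen by the same fold changes, so that value does not measure agreement. Without the libraries in doubt, the calls on the difference of the AA effects ended for B cell genes (median −0.0806, camera adjusted p = 0.572) and NRF2 genes (median −0.127, 0.962), with the test, far from the threshold, pointing the other way. Fewer genes are tested under the stricter filter; otherwise the cause was not tested. Single called lists kept direction and call in 1362 results and lost the call in 308. Named genes stayed as they were in 2091 results, lost a call in 104 and gained one in 61. Only the 3, 2 and 5 main calls could be lost, so most of the 2091 are genes that had no call to keep. Pseudocounts on normalised values did not apply and were not run. Depth limits genes near 0 in αβ with AA most, where the smallest library holds 6036487 counts.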

Other observations

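The tests of dendritic cells of any state and of depth in the γδ groups given in this part were chosen after the result was seen; the list of mature dendritic cells was prompted by leading genes seen in these data and written without them, before the values of its own genes were seen, and its median without members of fixed lists was added later.

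Genes known from mature, migratory dendritic cells had higher levels with AA in the libraries labelled γδ as a list, though none of them passed alone (smallest adjusted p = 0.206 for Socs2 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fscn1, which bundles actin in their dendrites, was at 1417 ± 960 CPM with AA and 76.6 ± 67.4 CPM without. The calcium channel gene Cacnb3 was at 481 and 19.3 CPM, a log2 fold change of 4.64 ± 1.03. Tmem123 was at 1239 and 395 CPM (1.65 ± 0.46) and the costimulatory gene Cd83 at 922 and 591 CPM (0.64 ± 0.50). Lower with AA were Ccl17 (−0.45 ± 1.78), Il4i1 (−1.68 ± 2.49) and Tnfrsf4 (−0.21 ± 1.71), all at group means under 5 CPM in γδ. A list of 28 such genes had a median log2 fold change of 1.46, above the 0.18 that marks the upper end of random lists of like expression, with 25 of 28 higher and 14 at an unadjusted p under 0.05. The median was 2.21 (upper end 0.23) over the 20 genes in no fixed list. RNA of mature dendritic cells is a candidate explanation, although the CD3 gate would remove them, T cells also express some of these genes, and 8 of the 28 are in a fixed list; the fixed dendritic cell list had a median of −0.35, which leaves more dendritic cells of any state open. A depth difference is argued against by a ratio of 0.939, and an effect of AA on the T cells themselves, which the design names, stays open.

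The share of counts from marker genes of other cell types varied between libraries of one group, although the sort was on CD3. Whether such cells were present was not tested. B cell genes made up 1.35%, 2.07% and 0.345% of the counts in αβ without AA and 0.264%, 0.475% and 1.52% in γδ without AA. Macrophage genes made up 0.214%, 0.193% and 2.43%, and 3.71%, 1.22% and 0.407%, in the same libraries. Mast cell and basophil genes made up 0.738%, 0.642% and 0.0773% in αβ with AA and 0.0935%, 0.0471% and 0.0481% in γδ with AA.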
